A study of Mus musculus with 17 samples.

How the data were processed

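The samples were whole lungs of mice from 5 genotype groups, 17 libraries in all, grouped by their labels into Control (3), Nlrp3 mutant (3), Il18r1 control (4), Nlrp3 mutant with Il18r1 het (3) and Nlrp3 mutant with Il18r1 null (4). Per the labels' protocols, RNA was purified with an RNeasy kit, stranded mRNA libraries were made with an Illumina kit and paired-end reads were taken on an Illumina NovaSeq. The labels give no age, sex or litter, and no statement that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

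Per the submitters' processing notes, STAR, a read aligner, was used with the genome build GRCm38 (mm10). The quantification tool and the gene annotation were not given in the sources used here. The authors deposited FPKM (fragments scaled by gene length and library size) per gene and library in 2 tables, 1 per experiment, each of 24354 lines. The headers name no unit; FPKM was inferred from the values, which were not whole, had no fixed sum and scaled with gene length, and from column names of the kind Cufflinks writes in the second table. Any scaling between libraries was not given in the sources used here. From each of them 27 lines whose gene name had turned into a date were left out and 24327 genes kept. The tables were taken as normalized separately, so tests were made only within a table. For the second experiment the authors also deposited 3 tables of comparisons, which per the file headers hold a mean normalized count, a log2 fold change with its standard error, a p-value and an adjusted p-value per gene, in the form DESeq2 writes, with summary lines as htseq-count writes them. The direction of their log2 fold changes was tested on the FPKM table. Summary lines such as reads without a gene carried 18.5% and 19.1% of the mean count in the tables of het and of null against control and were left out; the table of null against het held none of these lines. Genes can share reads with near-identical copies, and how such reads were counted was not given in the sources used here.

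FPKM is not a count, so genes were tested with limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1), which understates the change of low genes. Log2 fold changes and standard errors are on that scale, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05 and no limit on the fold. Genes at 1 FPKM or more in at least 3 libraries of a table were tested, 13549 in the first experiment and 13724 in the second. The first experiment was fitted with its 6 libraries, and the second with all 11, so that its 3 comparisons share an estimate of the spread. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

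Gene lists, 38 of cell type markers and pathways and 2 of handling and sex-linked genes, were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether members move one way on balance; the 2 quality lists are given as counts. A list's median and mean are over the log2 fold changes of its measured members. Named genes are Nlrp3, Il18r1, Il18, Il1b, Tnf and Lyz2 in each comparison, the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap and whose higher mean was at least 5 FPKM (without predicted genes and immunoglobulin or T cell receptor segments), and up to 4 members with the smallest p of each list. Acta2 and Rrm2 in null against control, and the genes of the X chromosome block, as well as further genes of the closing part, were named after their values were seen. Not every gene that this rule names is given. Chromosome positions are those of the GENCODE annotation of GRCm38, matched by gene symbol.

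Depth relative to the first library of a table was the most common ratio of FPKM values under 0.3, where few reads set the value, with 7.07% to 21.0% of those values at that ratio. No counting interval was made from FPKM. On simulated data, 10 draws with 200 changed genes among those tested, limma recovered 74.0% of genes changed by 0.5 in log2, 98.2% of those changed by 1 and 100% of those changed by 2 in the first experiment, with 4.89% of calls false. For changes of 0.5 the recovered share was 83.9% in het against control, 86.7% in null against control and 78.4% in null against het, with 3.98%, 4.85% and 4.43% of calls false. As a check of the unit, log2 of the authors' mean count over FPKM correlated with log2 exon length (r = 0.774 across 12710 genes, which are not independent replicates).

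Alternatives were a median-of-ratios rescaling, a pseudocount of 0.1, no expression filter or a mean of at least 5 FPKM, replicate numbers as a block, a robust fit with array weights, fits of 2 groups only, each library left out in turn, a log2 fold of at least 1, an adjusted p under 0.1, an estimated correlation for lists, a signature of the genes with the smallest p only and the signature without genes of myeloid lists. Rescaling to equal total FPKM, sex as a covariate and comparisons within 1 sex were added after the data were seen.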

Results

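Lungs of mice from 5 genotype groups were profiled by bulk RNA-seq in 17 libraries that formed 2 experiments. The first experiment held 3 control libraries and 3 libraries from mice that carried the Nlrp3 A350V allele together with LysM-cre, a driver active in myeloid cells. NLRP3 is the sensor of an inflammasome, a cytoplasmic complex through which the cytokines IL-1β and IL-18 mature, and A350V is a missense allele that makes the sensor overactive. The second experiment held 4 libraries of an Il18r1 control group, 3 libraries of the same Nlrp3 mutant with 1 intact copy of Il18r1, and 4 libraries of the mutant without an intact copy. Il18r1 encodes the chain of the IL-18 receptor that binds the cytokine. The question, as the series title words it, was how inflammasome overactivity disturbs the building of the alveolar gas exchange surface, and whether signalling by IL-18 and TNF lies in between. The groups are called the Nlrp3 mutant, the Il18r1 het mutant and the Il18r1 null mutant, each beside the control of its own experiment.

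Read totals per library could not be read from FPKM, so depth was estimated relative to the first library of each table. It ranged from 0.790 to 1 in the first experiment and from 0.747 to 1.15 in the second, with the lowest value in library 3 of the het mutant. Between 13147 and 13450 genes reached 1 FPKM per library, and the 10 most abundant genes held 10.7% to 16.0% of all FPKM. Total FPKM in the Nlrp3 mutant was 529612 ± 19824 (SD, n = 3) against 472007 ± 11062 (SD, n = 3) in the first experiment. In the second it was 547338 ± 11459.8 (SD, n = 3) in the het mutant, 473856 ± 8264 (SD, n = 4) in the null mutant and 488783 ± 7166 (SD, n = 4) in the control. Libraries of one group correlated across genes with r between 0.987 and 0.994, and no pair of libraries was identical.

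The targeted genes were read first in every library. Il18r1 (chromosome 1, 40465552 to 40500854, GRCm38) stood at 15.0, 14.0, 14.8 and 13.4 FPKM in the 4 Il18r1 control libraries, 30.7, 29.9 and 31.2 in the 3 het mutants and 6.98, 9.01, 8.59 and 8.46 in the 4 null mutants. The null libraries were the lowest of the experiment, although transcript remained. Which part of the gene was deleted was not given in the sources used here, so reads outside that part would still count in the remaining level. The het mutants, with 1 intact copy, lay above their controls. In the first experiment Il18r1 was at 22.1, 17.9 and 22.2 FPKM in the controls and 43.4, 40.0 and 41.3 in the mutants. Nlrp3 (chromosome 11, 59541568 to 59566956) was low in every library. It was at 0.973, 1.39 and 1.22 FPKM in the controls and 3.14, 2.73 and 2.95 in the mutants of the first experiment. In the second it was at 0.945, 2.00, 0.710 and 2.30 FPKM in the controls, 3.06, 4.08 and 3.63 in the het mutants and 3.59, 3.04, 4.00 and 3.58 in the null mutants. A missense allele is counted like the normal one, so the Nlrp3 level does not check that label.

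**Figure D1:**
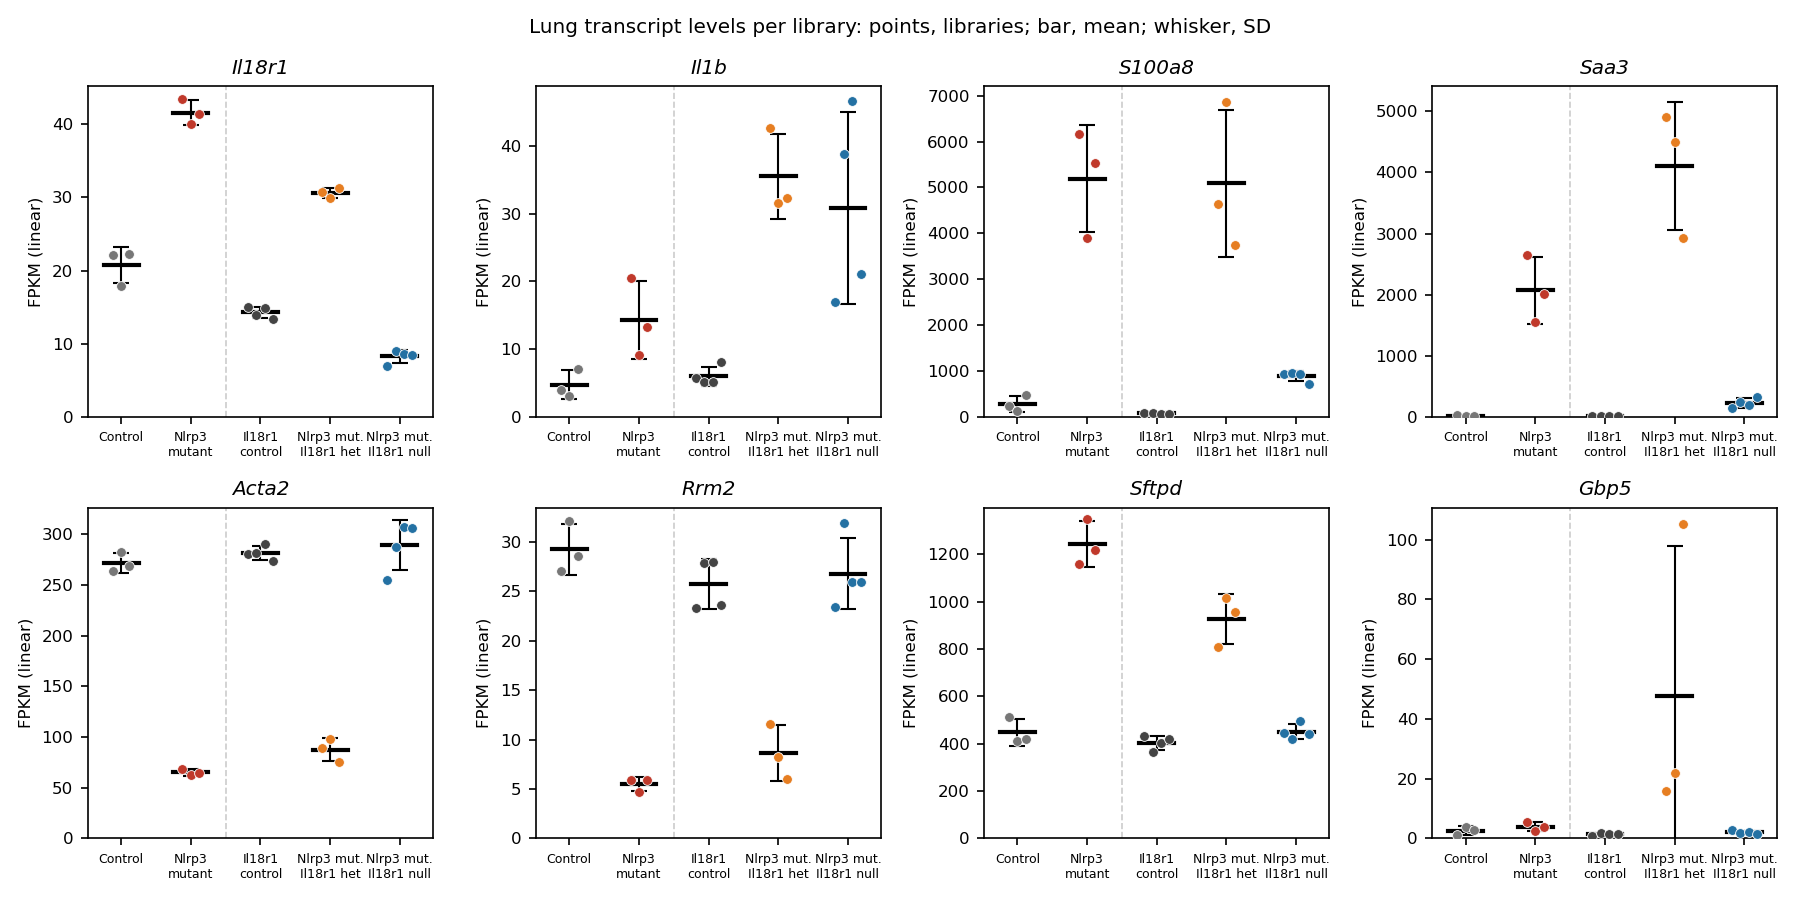
FPKM of Il18r1, Il1b, S100a8, Saa3, Acta2, Rrm2, Sftpd and Gbp5 in the 5 groups, with points for libraries, horizontal marks for group means and whiskers for 1 SD; the dashed line separates the experiments, which were taken as normalized separately. Saa3 went from 9.21 FPKM in the Il18r1 control to 4108 in the het mutant and 227 in the null mutant, while Acta2 went from 281 to 87.2 and 289.

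Sex-linked transcripts differed between groups. Xist, the RNA that silences one X chromosome in females, was above 1 FPKM in 8 libraries, where it was at least 37.7, and at most 0.0426 in the other 9. Those 8 were all 3 Nlrp3 mutants, all 3 het mutants and null libraries 2 and 4. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in the other 9, which were all 7 control libraries and null libraries 1 and 3. Within the null group, a contrast chosen after the values were seen set the 2 libraries with Xist against the 2 with Y-linked transcripts. It called 3 genes higher with Xist (Xist, Eif2s3x and Kdm6a) and 9 lower, with 562 of 13724 genes at unadjusted p under 0.05. The lower genes were the 4 Y-linked ones and Tmsb4x, Prps2, Msl3, Arhgap6 and Hccs, which are neighbours near the end of the X chromosome.

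**Figure D2:**
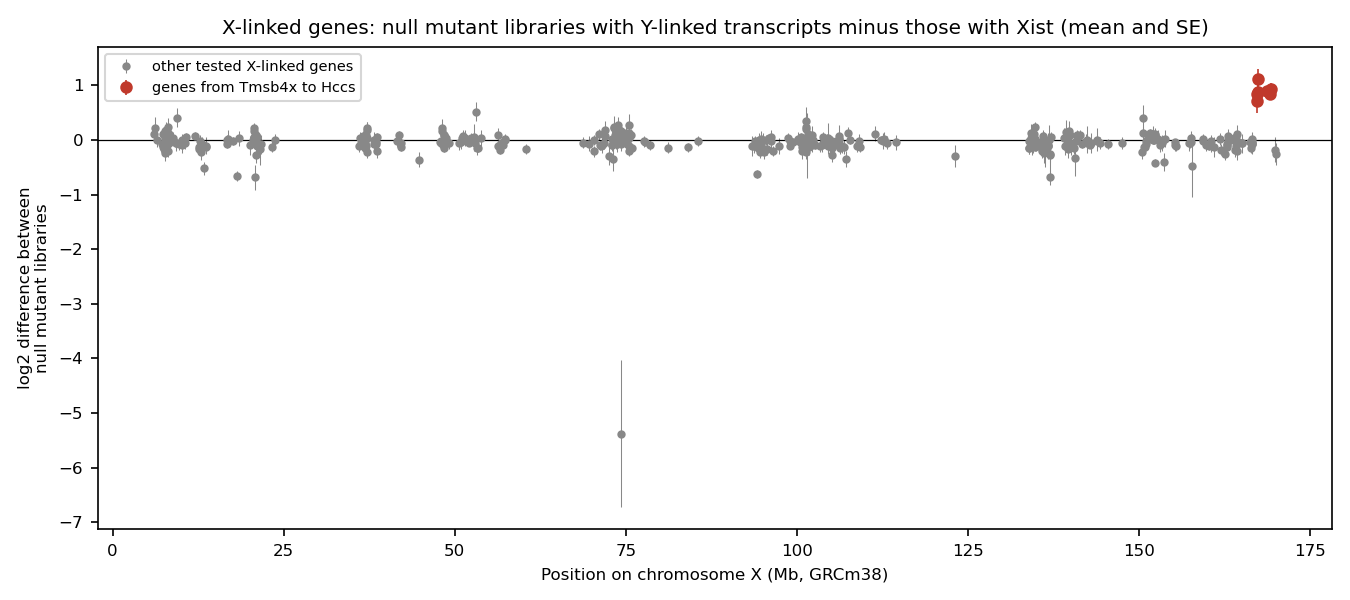
Difference in log2(FPKM + 1) between null mutant libraries with Y-linked transcripts and those with Xist (vertical axis) for the 427 tested genes of the X chromosome by position in Mb (horizontal axis, GRCm38). The 7 genes drawn in colour, Tmsb4x to Hccs, lie between 0.71 and 1.12.

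The first comparison asked what the Nlrp3 mutant changed in the lung. In mutant lungs S100a8, a subunit of the neutrophil protein calprotectin, went from 283 ± 173 to 5188 ± 1169.8 FPKM (SD, n = 3 each) and the acute phase gene Saa3 from 18.6 ± 14.3 to 2070.4 ± 544 FPKM (SD, n = 3 each). Surfactant protein D of the alveolar epithelium, Sftpd, went from 447 ± 55.5 to 1243 ± 96.2 FPKM (SD, n = 3 each). Acta2, the smooth muscle actin of contractile alveolar myofibroblasts, was lower and went from 272 ± 9.87 to 65.1 ± 3.22 FPKM (SD, n = 3 each), and Rrm2, a subunit of the enzyme that makes deoxynucleotides, from 29.2 ± 2.60 to 5.48 ± 0.720 FPKM (SD, n = 3 each). With limma 7528 of 13549 tested genes (55.6%) passed, 3788 of them higher and 3740 lower in the mutant, and 1096 of these changed by at least 1 in log2 (583 higher and 513 lower). The 3 mutants did not overlap with the 3 controls in 8704 tested genes, where chance gives 1 in 10.

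Of the 6 genes fixed for every comparison, 5 rose. Il18, the cytokine at the centre of the study's question, went from 7.24 ± 1.42 to 17.6 ± 3.23 FPKM (SD, n = 3 each) (log2 fold change 1.17, SE 0.15, adjusted p = 4.5e-04), and Il1b, the other inflammasome cytokine, from 4.72 ± 2.13 to 14.3 ± 5.71 FPKM (SD, n = 3 each) (log2 fold change 1.41, SE 0.31, adjusted p = 0.00591). The receptor gene Il18r1 rose (log2 fold change 0.98, SE 0.087, adjusted p = 7.4e-05), Nlrp3 itself rose (log2 fold change 0.85, SE 0.10, adjusted p = 3.2e-04) and so did Lyz2, the lysozyme gene whose locus drives the cre (log2 fold change 0.92, SE 0.16, adjusted p = 0.00204). Tnf was at 1.08 and 1.27 FPKM and did not pass (log2 fold change 0.12, SE 0.12, adjusted p = 0.432).

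Neutrophil markers (15 of 18 higher, median 2.38), granule precursor genes (7 of 8 higher, median 2.52), acute phase and antimicrobial genes (18 of 18 higher, median 1.97) and IL-17 response genes (8 of 8 higher, median 2.00) rose as groups. Camera gave adjusted p between 3.0e-10 and 3.9e-04 for these lists, and adjusted p between 0.306 and 0.310 with an estimated correlation. The 4 neutrophil genes with the smallest p were Il1r2, a decoy receptor for IL-1, (0.212 to 50.8 FPKM, log2 change 5.39, SE 0.19), Mmp9 (2.47, SE 0.14), Mmp8 (4.63, SE 0.28) and Cxcr2, the chemokine receptor that brings neutrophils into tissue, (3.73, SE 0.27). Examples of granule genes were Chil3 (5.78, SE 0.36) and Lcn2, which binds bacterial iron carriers, (3.14, SE 0.21). Among acute phase genes were Serpina3n, a protease inhibitor, (0.929 to 308 FPKM, log2 change 7.32, SE 0.058), Cp, ceruloplasmin, (1.68, SE 0.048), and Cfb, complement factor B, (3.28, SE 0.15), and Serpina3n belongs to a family of near-identical copies. Inflammasome and IL-1 family genes (18 of 22 higher, median 0.80), TNF and NF-kB response genes (17 of 26 higher, median 0.70) and matrix proteases and inhibitors (8 higher and 3 lower of 15, median 0.98) were higher. For these lists camera gave adjusted p between 5.1e-06 and 0.0372, and adjusted p between 0.306 and 0.472 with an estimated correlation. Casp4, the sensor protease for intracellular lipopolysaccharide, changed by 1.75 (SE 0.14) and Il18rap, the second receptor chain for IL-18, by 1.78 (SE 0.15). Adjusted over the list alone, these counts were the same except for neutrophil markers (16 higher), granule precursor genes (8 higher) and matrix proteases and inhibitors (9 higher and 3 lower).

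Other blood and immune lineages moved apart. Among interstitial macrophage markers, 11 of 14 rose and 3 did not pass (median 1.31, camera adjusted p = 2.9e-06, adjusted p = 0.306 with an estimated correlation). The complement genes C1qa (53.6 to 143 FPKM, log2 change 1.40, SE 0.056) and C1qc (1.59, SE 0.080) rose, as did the haemoglobin scavenger receptor Cd163 (2.10, SE 0.083). From the set of alveolar macrophage markers, 13 of 17 rose and 4 did not pass (median 1.00, camera adjusted p = 7.8e-05, adjusted p = 0.306 with an estimated correlation). For monocyte markers, 4 of 13 rose, 5 fell and 4 did not pass (median 0.049 and -0.11 at equal total FPKM, mean -0.25, camera direction lower, camera adjusted p = 0.808). Within it, F13a1 (5.08 to 24.7 FPKM, log2 change 2.08, SE 0.088) and Ly6c2 (1.23, SE 0.17) rose, while Nr4a1 (-1.91, SE 0.11) and Vcan (-1.64, SE 0.15) fell. Among platelet and megakaryocyte genes, 9 of 9 rose (median 1.88, camera adjusted p = 5.1e-06, adjusted p = 0.306 with an estimated correlation). The chemokine genes of platelet granules, Pf4 (2.24, SE 0.12) and Ppbp (2.35, SE 0.16), were among them. Among B cell markers, 4 of 5 fell and 1 did not pass (median -1.35, camera adjusted p = 0.00386, adjusted p = 0.306 with an estimated correlation). The B cell receptor component Cd79a (6.30 to 0.967 FPKM, log2 change -1.88, SE 0.16) and the surface antigen Ms4a1 (-2.00, SE 0.16) fell. Erythroid genes (8 of 9 lower, median -1.96) were lower. The camera test gave adjusted p = 2.3e-04 for this list, and adjusted p = 0.306 with an estimated correlation. T and NK cell markers (4 of 7 lower, median -0.62), dendritic cell markers (1 higher and 5 lower of 8, median -0.82) and type 2 lymphoid, mast cell, basophil and eosinophil markers (2 higher and 5 lower of 7, median -0.78) were not called by camera. The calls of the T cell genes Ccl5 and Cd3g each ended in 4 of 6 fits without 1 library (adjusted p of up to 0.146 and 0.0897). When adjusted over the list alone, these counts were the same except for monocyte markers (5 higher and 5 lower), alveolar macrophage markers (15 higher), interstitial macrophage markers (12 higher), dendritic cell markers (2 higher and 5 lower) and erythroid genes (9 lower).

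Surfactant-making type 2 (AT2) markers (16 of 18 higher, median 0.65), type 1 alveolar epithelial (AT1) markers (15 higher and 1 lower of 19, median 0.55), markers of transitional epithelium (12 higher and 1 lower of 14, median 0.87), airway epithelial markers (13 of 14 higher, median 0.92) and mesothelial markers (8 of 8 higher, median 0.79) were higher. With camera these lists had adjusted p between 5.4e-07 and 7.0e-04, and adjusted p between 0.306 and 0.310 with an estimated correlation. Examples of AT2 genes were Slc34a2, a phosphate transporter, (499 to 1094 FPKM, log2 change 1.13, SE 0.068), S100g (151 to 418 FPKM, log2 change 1.46, SE 0.073) and Abca3, which loads lipid into lamellar bodies, (0.70, SE 0.050). Among AT1 genes, Lmo7 (1.07, SE 0.066), Clic5 (0.62, SE 0.047) and Scnn1g, a sodium channel subunit, (1.18, SE 0.081) rose, and among transitional ones Krt19 (0.99, SE 0.071), Lgals3 (1.10, SE 0.081) and Cldn4 (1.97, SE 0.16). The airway secretory protein gene Scgb3a1 (116 to 924 FPKM, log2 change 3.01, SE 0.19) rose. Surfactant lipid synthesis genes (10 higher and 7 lower of 20, median 0.12 and -0.037 at equal total FPKM, mean -0.010, camera direction higher) were not called by camera. Fads1 (-0.74) fell and Scd1 (0.60) rose. As adjusted over the list alone, each of these counts was the same.

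Alveolar myofibroblast and smooth muscle markers (2 higher and 13 lower of 18, median -0.75), pericyte markers (10 of 10 lower, median -0.60), elastic fibre and matrix assembly genes (2 higher and 21 lower of 25, median -0.75) and proliferation genes (26 of 26 lower, median -1.94) were lower. Camera gave adjusted p between 5.9e-15 and 1.8e-04 for these lists, and adjusted p between 0.306 and 0.310 with an estimated correlation. Beside Acta2, Tagln, an actin-binding protein, (327 to 114 FPKM, log2 change -1.50, SE 0.057), Pdlim3 (-1.85, SE 0.089) and P2ry14 (-1.73, SE 0.072) fell, as did the growth factor receptor Pdgfrb (-0.39, SE 0.047) and the proteoglycan Cspg4 (-1.07, SE 0.13) of pericytes. The matrix protein Tnc, tenascin C, (142 to 27.0 FPKM, log2 change -2.38, SE 0.14), the fibrillin Fbn2 (-1.31, SE 0.077) and the crosslinking enzyme Loxl2 (-0.98, SE 0.050) fell, while Lox, another crosslinking enzyme, (45.7 to 182 FPKM, log2 change 1.97, SE 0.081) rose. The proliferation genes included Cdc20 (26.5 to 5.80 FPKM, log2 change -2.01, SE 0.10), Plk1 (-1.74, SE 0.083) and Aurkb (-1.94, SE 0.097), which act in mitosis. Alveolar and lipofibroblast markers (7 higher and 7 lower of 16, median 0.0098 and -0.15 at equal total FPKM) and TGF-beta response genes (5 higher and 5 lower of 16, median 0.024 and -0.14 at equal total FPKM, mean -0.17, camera direction lower) were not called by camera. Plin2 (0.91) and Inmt (4.05) rose and Itga8 (-0.80) and Figf (-1.25) fell. With p adjusted over the list alone, each of these counts was the same.

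Among pan-endothelial markers, 2 of 13 rose, 7 fell and 4 did not pass (median -0.24, camera adjusted p = 0.0544). The transcription factors Sox17 (-0.81, SE 0.078) and Sox18 (-0.73, SE 0.074) fell. General capillary markers (3 higher and 3 lower of 13, median 0.012 and -0.15 at equal total FPKM), aerocyte (alveolar capillary) markers (6 higher and 6 lower of 13, median -0.21, mean 0.0070, camera direction lower) and angiogenesis and alveolar growth factor genes (7 higher and 15 lower of 31, median -0.12) were not called by camera. Aplnr, the apelin receptor, went from 97.9 to 31.2 FPKM and Lpl, lipoprotein lipase, from 23.1 to 122. Wnt5a (-1.01) and the cell cycle factor Foxm1 (-1.93) fell. Among hypoxia and glycolysis genes, 8 of 17 rose, 1 fell and 8 did not pass (median 0.18, camera adjusted p = 0.0135, adjusted p = 0.306 with an estimated correlation). For interferon-gamma response genes, 2 of 25 rose, 6 fell and 17 did not pass (median 0.070 and -0.067 at equal total FPKM, mean -0.14, camera direction lower, camera adjusted p = 0.741). Those that fell included the antigen-presenting class II genes H2-Aa (108 to 26.6 FPKM, log2 change -2.00, SE 0.16) and H2-Eb1 (-1.85, SE 0.16). Among type I interferon response genes, 2 of 21 rose, 5 fell and 14 did not pass (median -0.26, camera adjusted p = 0.328). Adjusted over the list alone, these counts were the same except for pan-endothelial markers (2 higher and 8 lower) and type I interferon response genes (2 higher and 4 lower).

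Lists of neighbouring tissues and of sample handling were read beside these. Among heart and skeletal muscle genes, 6 of 11 rose, 1 fell and 4 did not pass (median 0.61, camera adjusted p = 0.0322, adjusted p = 0.472 with an estimated correlation). Cardiac troponin T, Tnnt2 (1.15, SE 0.10), rose and myoglobin, Mb (-2.17, SE 0.37), fell. Of fat cell genes, 1 of 2 rose and 1 fell (median 0.088 and -0.029 at equal total FPKM, mean 0.088, camera direction lower, camera adjusted p = 0.974). Only Tcf7 of the thymus list was tested, and it fell (log2 fold change -1.08, SE 0.059, adjusted p = 1.1e-05). Among immediate early and handling genes, 8 of 14 rose, 2 fell and 4 did not pass (median 0.48). Nr4a1 and Egr1 (-1.22) fell and Klf6 (0.90) rose. Among sex-linked genes, 1 of 5 rose and 4 fell (median -2.94). When adjusted over the list alone, each of these counts was the same.

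Outside these lists, the largest rises also included Asprv1 (4.00 to 129 FPKM, log2 change 4.85, SE 0.36), Ifitm6 (4.34, SE 0.36) and BC100530 (4.22, SE 0.44), the last from a family of near-identical stefin genes. The largest falls included Ptpn5 (9.64 to 0.141 FPKM, log2 change -3.22, SE 0.11), Prss35 (-2.90, SE 0.16), Slitrk6 (-2.78, SE 0.15), Fam64a (-2.73, SE 0.14) and Etv4 (-2.61, SE 0.12), the last a transcription factor downstream of fibroblast growth factor. The short RNAs Mir703 (566 FPKM in the controls) and Snora81 (11.1) were listed at 0 in every mutant library, as were the Y-linked Eif2s3y and Kdm5d, so no fold is given for them. Camera called 23 of 37 lists, 17 higher and 6 lower; with an estimated correlation the lowest adjusted p was 0.306, and fry called 29. All mutants carried Xist and all controls Y-linked transcripts, so sex and genotype could not be told apart here. With every library set to the same total FPKM, limma called 2391 genes higher and 5613 lower (29.9% higher, against 50.3%), and the median change of all genes was -0.15 in place of 0.0023.

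**Figure D3:**
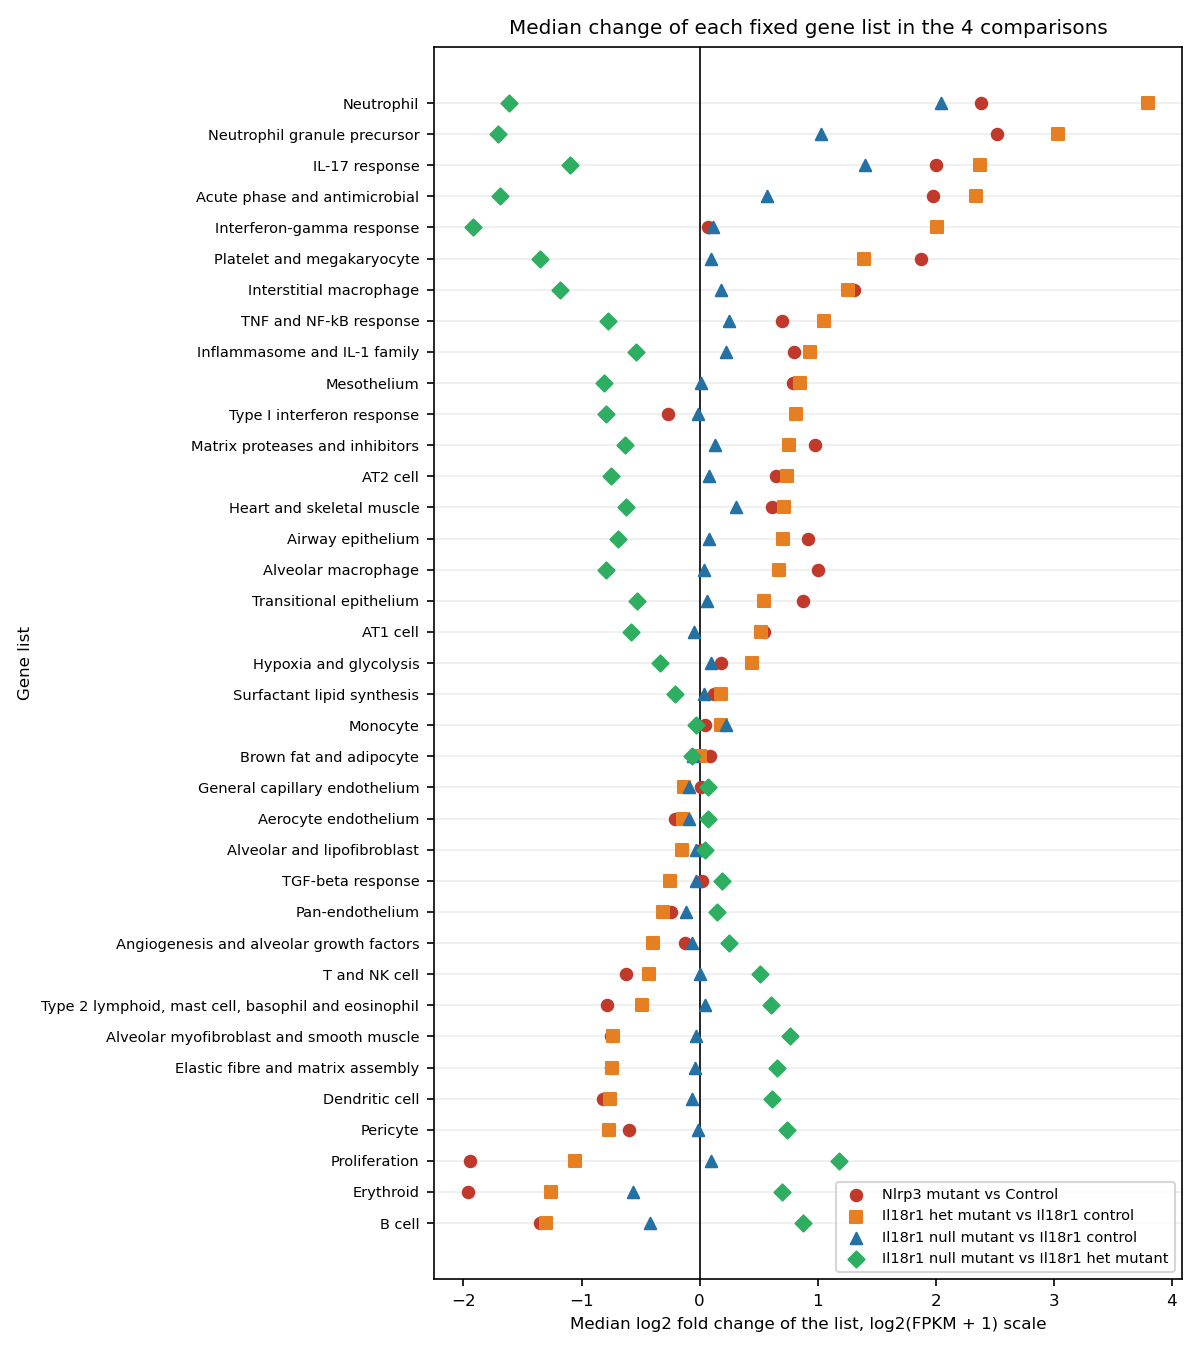
Median log2 fold change of the members of each gene list tested in all 4 comparisons (horizontal axis, log2(FPKM + 1) scale), 1 symbol and colour per comparison, with lists on the vertical axis. The neutrophil list has medians of 2.38, 3.80, 2.04 and -1.62 and the proliferation list -1.94, -1.05, 0.10 and 1.18, in the order first mutant, het mutant, null mutant and null against het.

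The second comparison set the Il18r1 het mutant against the Il18r1 control and so asked whether the mutant change was present with 1 intact copy of the receptor gene. S100a8 and Saa3 were again higher, S100a8 going from 75.8 ± 12.5 (SD, n = 4) to 5085 ± 1609.7 FPKM (SD, n = 3) and Saa3 from 9.21 ± 3.06 (SD, n = 4) to 4108 ± 1049 FPKM (SD, n = 3). Sftpd went from 403 ± 29.6 (SD, n = 4) to 927 ± 107 FPKM (SD, n = 3). Acta2 was lower, from 281 ± 7.10 (SD, n = 4) to 87.2 ± 11.3 FPKM (SD, n = 3), and so was Rrm2, from 25.7 ± 2.54 (SD, n = 4) to 8.60 ± 2.84 FPKM (SD, n = 3). Irf1, a transcription factor of the interferon-gamma response, went from 34.5 ± 2.54 (SD, n = 4) to 142 ± 56.1 FPKM (SD, n = 3). With limma 7716 of 13724 genes (56.2%) passed, 3752 higher and 3964 lower in the het mutant, 1067 of them by at least 1 in log2 (741 higher and 326 lower). Groups did not overlap in 7748 tested genes, where chance gives 2 in 35.

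Of the genes fixed for every comparison, Il1b rose from 5.99 ± 1.43 (SD, n = 4) to 35.5 ± 6.24 FPKM (SD, n = 3) (log2 fold change 2.39, SE 0.29, adjusted p = 2.9e-05), and Il18 (log2 fold change 0.97, SE 0.15, adjusted p = 2.3e-04), Il18r1 (log2 fold change 1.05, SE 0.073, adjusted p = 3.8e-07) and Nlrp3 (log2 fold change 0.93, SE 0.20, adjusted p = 0.00188) rose. Tnf went from 0.861 ± 0.157 (SD, n = 4) to 1.63 ± 0.642 FPKM (SD, n = 3) and passed although its groups overlapped (log2 fold change 0.47, SE 0.18, adjusted p = 0.0370). The Tnf call ended without control library 1, 2 or 3 or het library 1 or 2, with adjusted p of up to 0.171. Lyz2 did not pass (log2 fold change 0.46, SE 0.21, adjusted p = 0.0797). In the authors' deposited table for this comparison Tnf had a log2 fold change of 1.01 with adjusted p = 0.00490.

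Neutrophil markers (17 of 18 higher, median 3.80), granule precursor genes (10 of 10 higher, median 3.03), acute phase and antimicrobial genes (18 of 18 higher, median 2.34) and IL-17 response genes (8 of 8 higher, median 2.37) were higher. For these lists camera gave adjusted p between 4.3e-12 and 2.3e-05, and adjusted p between 0.130 and 0.183 with an estimated correlation. Besides S100a8, the calprotectin partner S100a9 (156 to 8289 FPKM, log2 change 5.69, SE 0.21), the collagenase Mmp8 (2.58 to 178 FPKM, log2 change 5.60, SE 0.22) and Retnlg (5.55 to 269 FPKM, log2 change 5.26, SE 0.24) were on the neutrophil list. Granule genes Ngp (31.1 to 1317 FPKM, log2 change 5.33, SE 0.26) and Ltf, lactoferrin, (4.85, SE 0.25) rose with the granulocyte factor Cebpe (2.97, SE 0.11). Slpi, a protease inhibitor, went from 6.33 to 119 FPKM and Hp, haptoglobin, from 302 to 2817. Inflammasome and IL-1 family genes (20 of 23 higher, median 0.93), TNF and NF-kB response genes (24 of 29 higher, median 1.06) and matrix proteases and inhibitors (9 higher and 3 lower of 17, median 0.76) were higher too. The camera test gave adjusted p between 8.0e-08 and 0.00826 for these lists, and adjusted p between 0.130 and 0.204 with an estimated correlation. The NF-kB feedback genes Nfkbia (56.9 to 246 FPKM, log2 change 2.08, SE 0.14) and Tnfaip3 (7.89 to 36.3 FPKM, log2 change 2.05, SE 0.14) rose. As adjusted over the list alone, these counts were the same except for TNF and NF-kB response genes (25 higher and 1 lower).

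Among interferon-gamma response genes, 22 of 26 rose, 1 fell and 3 did not pass (median 2.01, camera adjusted p = 7.4e-07, adjusted p = 0.313 with an estimated correlation). The immunity-related GTPases Igtp (10.1 to 160.4 FPKM, log2 change 3.54, SE 0.42) and Irgm2 (2.99, SE 0.32) and the guanylate-binding protein Gbp4 (9.89 to 100.2 FPKM, log2 change 2.99, SE 0.34) were examples, and such families share similar sequences. Het library 3 was the highest, with Gbp5 at 15.7, 21.8 and 105 FPKM in libraries 1, 2 and 3. Without that library, 21 of 25 members rose and 4 fell, with a median of 1.64. Among type I interferon response genes, 13 of 22 rose, 2 fell and 7 did not pass (median 0.82, camera adjusted p = 0.00360, adjusted p = 0.529 with an estimated correlation). Oas2 (1.82, SE 0.19) and Zbp1 (2.95, SE 0.45) rose. In the first experiment the same interferon-gamma list had 2 members higher and 6 lower, and the difference between the experiments was not tested. Interstitial macrophage markers (13 of 14 higher, median 1.26), alveolar macrophage markers (13 higher and 1 lower of 17, median 0.67) and platelet and megakaryocyte genes (8 of 8 higher, median 1.39) were higher. With camera these lists had adjusted p between 8.0e-08 and 5.9e-04, and adjusted p between 0.130 and 0.280 with an estimated correlation. Complement genes C1qc (48.0 to 189 FPKM, log2 change 1.95, SE 0.094) and C1qb (1.94, SE 0.12) and the scavenger receptor Marco (2.23, SE 0.098) rose. Monocyte markers (6 higher and 2 lower of 14, median 0.18) were not called by camera. With p adjusted over the list alone, these counts were the same except for type I interferon response genes (16 higher and 2 lower).

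B cell markers (8 of 8 lower, median -1.30), erythroid genes (9 of 9 lower, median -1.26), dendritic cell markers (1 higher and 6 lower of 9, median -0.76) and thymus genes (2 of 2 lower, median -1.0) were lower. Camera gave adjusted p between 6.0e-05 and 0.0348 for these lists, and adjusted p between 0.183 and 0.280 with an estimated correlation. Cd79a went from 11.2 to 0.538 FPKM, and Hbb-b1, a beta-globin gene with near-identical copies, from 18892 to 6382. T and NK cell markers (1 higher and 5 lower of 10, median -0.43) and type 2 lymphoid, mast cell, basophil and eosinophil markers (1 higher and 4 lower of 8, median -0.49) were not called by camera. Adjusted over the list alone, each of these counts was the same.

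Surfactant-making type 2 (AT2) markers (17 of 18 higher, median 0.74), type 1 alveolar epithelial (AT1) markers (17 higher and 1 lower of 19, median 0.52), markers of transitional epithelium (12 higher and 2 lower of 15, median 0.55), airway epithelial markers (11 higher and 1 lower of 14, median 0.71) and mesothelial markers (7 of 8 higher, median 0.85) were higher. For these lists camera gave adjusted p between 9.3e-08 and 5.5e-04, and adjusted p between 0.138 and 0.285 with an estimated correlation. Surfactant protein A, Sftpa1 (567 to 1405 FPKM, log2 change 1.31, SE 0.077), and the AT2 lysozyme Lyz1 (650.3 to 1883 FPKM, log2 change 1.52, SE 0.11) rose, as did podoplanin, Pdpn (70.9 to 147 FPKM, log2 change 1.04, SE 0.056), a membrane protein of AT1 cells. The AT1 marker Igfbp2 (246 to 76.8 FPKM, log2 change -1.67, SE 0.14) fell. Surfactant lipid synthesis genes (11 higher and 5 lower of 20, median 0.18) were not called by camera. When adjusted over the list alone, each of these counts was the same.

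Alveolar myofibroblast and smooth muscle markers (2 higher and 14 lower of 18, median -0.73), pericyte markers (10 of 10 lower, median -0.77), elastic fibre and matrix assembly genes (2 higher and 19 lower of 25, median -0.74) and proliferation genes (26 of 26 lower, median -1.05) were lower. The camera test gave adjusted p between 5.7e-09 and 1.5e-05 for these lists, and adjusted p between 0.156 and 0.278 with an estimated correlation. Examples were Pdlim3 (-1.75, SE 0.096), P2ry14 (-1.97, SE 0.11) and Pdgfrb (-1.04, SE 0.068). Tnc (-2.13, SE 0.11) and the collagen gene Col1a1 (-1.29, SE 0.073) fell, and Lox (1.59, SE 0.084) rose. Pan-endothelial markers (1 higher and 8 lower of 13, median -0.31) and angiogenesis and alveolar growth factor genes (3 higher and 16 lower of 31, median -0.40) were lower. With camera these lists had adjusted p between 0.00368 and 0.0348, and adjusted p between 0.173 and 0.407 with an estimated correlation. Hypoxia and glycolysis genes (11 higher and 1 lower of 17, median 0.44) were higher. Camera gave adjusted p = 3.5e-04 for this list, and adjusted p = 0.194 with an estimated correlation. Slc2a1, a glucose transporter, went from 8.83 to 23.6 FPKM and Lef1, a nuclear effector of Wnt signalling, from 6.38 to 1.45. General capillary markers (3 higher and 6 lower of 13, median -0.13), aerocyte (alveolar capillary) markers (6 higher and 5 lower of 13, median -0.14, mean 0.013, camera direction higher), alveolar and lipofibroblast markers (6 higher and 6 lower of 16, median -0.15), TGF-beta response genes (4 higher and 7 lower of 16, median -0.25), heart and skeletal muscle genes (5 higher and 1 lower of 13, median 0.72) and fat cell genes (1 of 2 higher, median 0.0051 and -0.67 at equal total FPKM) were not called by camera. The lists read for sample quality were handling genes (7 higher and 3 lower of 15, median 0.33) and sex-linked genes (1 higher and 4 lower of 5, median -2.97). As adjusted over the list alone, these counts were the same except for alveolar myofibroblast and smooth muscle markers (2 higher and 15 lower).

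The largest rises outside these lists, in log2, included Asprv1 (6.12, SE 0.17), Serpina3f (6.06, SE 0.35) and Serpina3g (5.54, SE 0.26), and the largest falls Ly6d (-3.60, SE 0.26), Ptpn5 (-3.37, SE 0.10), Crabp1 (-3.19, SE 0.26) and Slitrk6 (-2.78, SE 0.14). Camera called 28 of 38 lists, 18 higher and 10 lower, and fry 33; with an estimated correlation camera's lowest adjusted p was 0.130. All het mutants carried Xist and all controls Y-linked transcripts. With sex as a covariate, which the null group alone can separate, limma called 4883 genes (2436 higher and 2447 lower), and at equal total FPKM 2484 higher and 6482 lower, with a median of -0.16 in place of -0.017.

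The third comparison asked how the mutant without an intact copy of Il18r1 differed from the control. S100a8 and Saa3 were higher, S100a8 going from 75.8 ± 12.5 to 890.5 ± 118 FPKM (SD, n = 4 each) and Saa3 from 9.21 ± 3.06 to 227 ± 76.2 FPKM (SD, n = 4 each). Followed on from the other comparisons, Acta2 was at 281 ± 7.10 FPKM (SD, n = 4) in the control and 289 ± 24.7 (SD, n = 4) in the null mutant, with adjusted p = 0.942 by limma. Sftpd (403 and 449.9 FPKM, adjusted p = 0.575) and Rrm2 (25.7 and 26.8 FPKM, adjusted p = 0.957) did not pass either. With limma 270 of 13724 genes (1.97%) passed, 256 higher and 14 lower in the null mutant, and the 103 that changed by at least 1 in log2 were all higher. Without single libraries the number of lower genes fell to 5 (control 2), 6 (null 2), 7 (null 3), 8 (control 4 or null 4) and 9 (control 1). It was 52 in a robust fit with array weights and 125 of 649 genes in the authors' deposited table. The 4 null and 4 control libraries did not overlap in 1160 tested genes, where chance gives 1 in 35.

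Il18r1 was lower in the null mutant (log2 fold change -0.73, SE 0.068, adjusted p = 8.4e-05). Il1b rose from 5.99 ± 1.43 to 30.9 ± 14.2 FPKM (SD, n = 4 each) (log2 fold change 2.10, SE 0.27, adjusted p = 9.5e-04) and Nlrp3 rose (log2 fold change 0.92, SE 0.19, adjusted p = 0.0219). The Nlrp3 call ended without control library 1 or null library 1, 3 or 4, with adjusted p of up to 0.0788. The other 3 genes fixed in advance did not pass. Il18 went from 5.26 to 6.40 FPKM (log2 fold change 0.22, SE 0.14, adjusted p = 0.686), Tnf from 0.861 to 1.06 (log2 fold change 0.13, SE 0.16, adjusted p = 0.873) and Lyz2 from 1595 to 1222 (log2 fold change -0.33, SE 0.19, adjusted p = 0.649). In the authors' deposited table for this comparison Il18r1 changed by -0.44 (adjusted p = 2.2e-07).

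Neutrophil markers (16 of 18 higher, median 2.04), acute phase and antimicrobial genes (7 of 18 higher, median 0.57), IL-17 response genes (4 of 8 higher, median 1.40) and granule precursor genes (6 of 10 higher, median 1.03) were higher. For these lists camera gave adjusted p between 6.5e-48 and 1.3e-13, and adjusted p between 0.0232 and 0.0246 with an estimated correlation. Beside S100a8 the neutrophil genes included S100a9 (156 to 1667 FPKM, log2 change 3.42, SE 0.20), Retnlg (3.49, SE 0.22) and Csf3r, the receptor for granulocyte colony-stimulating factor, (2.28, SE 0.16). Acute phase examples were Slpi (6.33 to 26.9 FPKM, log2 change 1.93, SE 0.10), Cfb (2.19, SE 0.16) and Lrg1 (2.58, SE 0.28), and granule examples Ltf (2.05, SE 0.23), Ngp (2.08, SE 0.24) and Lcn2 (1.38, SE 0.21). Inflammasome and IL-1 family genes (5 higher and 1 lower of 23, median 0.22), monocyte markers (3 of 14 higher, median 0.22) and matrix proteases and inhibitors (6 of 17 higher, median 0.13) were higher. The camera test gave adjusted p between 1.6e-09 and 4.5e-06 for these lists, and adjusted p between 0.0246 and 0.0382 with an estimated correlation. Il18rap went from 1.04 to 4.29 FPKM, and the member that fell was Il18r1 itself. Ccr2, the chemokine receptor of inflammatory monocytes, went from 7.24 to 19.4 FPKM and Ly6c2 from 16.4 to 32.1. Mmp9 (2.57, SE 0.19) and Mmp8 (2.57, SE 0.21), both also on the neutrophil list, rose. With p adjusted over the list alone, these counts were the same except for neutrophil markers (17 higher), acute phase and antimicrobial genes (13 higher), IL-17 response genes (6 higher), granule precursor genes (8 higher), inflammasome and IL-1 family genes (11 higher and 1 lower) and monocyte markers (6 higher).

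These 7 lists were the ones that held with an estimated correlation. Camera called 16 of 38 lists with the preset correlation, 11 higher and 5 lower, and fry 9. Interstitial macrophage markers (2 of 14 higher, median 0.19), TNF and NF-kB response genes (1 of 29 higher, median 0.25) and hypoxia and glycolysis genes (1 of 17 higher, median 0.099) were higher. With camera these lists had adjusted p between 8.4e-08 and 0.00417, and adjusted p between 0.144 and 0.352 with an estimated correlation. The 2 macrophage genes were C1qb, whose call ended in 7 of 8 fits without 1 library, and C1qc, whose call ended in 3 (adjusted p of up to 0.141 and 0.0634). The TNF-induced gene Tnfaip2 (7.32 to 14.1 FPKM, log2 change 0.85, SE 0.12) was the member of the TNF list that rose. B cell markers (2 of 8 lower, median -0.42) and erythroid genes (2 of 9 lower, median -0.56) were lower. Camera gave adjusted p between 8.4e-07 and 6.3e-06 for these lists, and adjusted p between 0.120 and 0.281 with an estimated correlation. The call of the B cell gene Fcmr ended in 6 of 8 fits without 1 library (adjusted p of up to 0.0938). Among proliferation genes limma called 0 of 26, with 0 at unadjusted p under 0.05 (median 0.10, camera adjusted p = 0.0159, adjusted p = 0.796 with an estimated correlation). Among pan-endothelial markers limma called 0 of 13, with 2 at unadjusted p under 0.05 (median -0.12, camera adjusted p = 0.00181, adjusted p = 0.352 with an estimated correlation). Of angiogenesis and alveolar growth factor genes limma called 0 of 31, with 6 at unadjusted p under 0.05 (median -0.065, camera adjusted p = 0.00816, adjusted p = 0.172 with an estimated correlation). Among dendritic cell markers limma called 0 of 9, with 2 at unadjusted p under 0.05 (median -0.063, camera adjusted p = 0.0353, adjusted p = 0.315 with an estimated correlation). Adjusted over the list alone, these counts were the same except for interstitial macrophage markers (3 higher), TNF and NF-kB response genes (6 higher), B cell markers (5 lower), erythroid genes (6 lower) and dendritic cell markers (1 lower).

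The remaining lists for cell types and pathways were not called by camera in this comparison. Among surfactant-making type 2 (AT2) markers, 2 of 18 rose and 16 did not pass (median 0.082, camera adjusted p = 0.104). Of these the call of Chil1 ended in 4 of 8 fits without 1 library (adjusted p of up to 0.0812). For aerocyte (alveolar capillary) markers, 1 of 13 rose and 12 did not pass (median -0.088, camera adjusted p = 0.165). In each remaining list limma called 0 members. The numbers at unadjusted p under 0.05 were, for the epithelium, type 1 alveolar epithelial (AT1) markers (2 of 19), surfactant lipid synthesis genes (1 of 20), markers of transitional epithelium (2 of 15), airway epithelial markers (7 of 14) and mesothelial markers (1 of 8). For the mesenchyme and capillaries they were alveolar myofibroblast and smooth muscle markers (2 of 18), pericyte markers (2 of 10), elastic fibre and matrix assembly genes (5 of 25), alveolar and lipofibroblast markers (2 of 16), TGF-beta response genes (1 of 16) and general capillary markers (3 of 13). For immune and blood lists they were alveolar macrophage markers (7 of 17), T and NK cell markers (1 of 10), type 2 lymphoid, mast cell, basophil and eosinophil markers (1 of 8), platelet and megakaryocyte genes (0 of 8), interferon-gamma response genes (1 of 26) and type I interferon response genes (2 of 22), and for neighbouring tissues heart and skeletal muscle genes (3 of 13), fat cell genes (0 of 2) and thymus genes (0 of 2). Handling genes had 1 of 15 and sex-linked genes 5 of 5 at unadjusted p under 0.05, with 0 called by limma. Medians, means and camera directions differed in sign for T and NK cells, fat cells, the type I interferon response and the TGF-beta response, whose medians were 0.00073, -0.057, -0.013 and -0.031. At equal total FPKM the medians changed sign for the lipofibroblast, myofibroblast, pericyte, elastic fibre, fat cell, type I interferon and TGF-beta lists, where they were 0.0079, 0.0049, 0.027, 0.0011, 0.057, 0.024 and 0.013. When adjusted over the list alone, these counts were the same except for markers of transitional epithelium (1 higher), airway epithelial markers (3 higher and 3 lower), alveolar macrophage markers (1 higher), type 2 lymphoid, mast cell, basophil and eosinophil markers (1 higher) and sex-linked genes (1 higher and 4 lower).

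Among the largest rises were also Stfa2 (30.4 to 351 FPKM, log2 change 3.48, SE 0.23), Stfa3 (3.08, SE 0.26) and BC100530 (3.14, SE 0.18), from a family of near-identical stefin genes, Asprv1 (3.47, SE 0.15) and Wfdc21 (3.17, SE 0.23), and Snord22, a short RNA listed at 0 in 3 control libraries. Among genes with a mean of at least 5 FPKM, the largest falls beside Il18r1 were small: Cd79a (11.2 to 6.20 FPKM, log2 change -0.76, SE 0.14), Hbb-b1 (18892 to 11424 FPKM, log2 change -0.70, SE 0.16), Hba-a1 (3503 to 2134 FPKM, log2 change -0.69, SE 0.16), Vtn (-0.43, SE 0.098), Agt (-0.30, SE 0.068), Cdh16 (-0.26, SE 0.052), Mrps36 (-0.25, SE 0.046) and Ptges (-0.25, SE 0.049). Leaving out 1 library ended the calls for Hbb-b1, Vtn, Cdh16 and Snord22 in 7 of 8 fits each, for Hba-a1 and Ptges in 6 each and for Agt in all 8, with adjusted p of up to 0.154. Against controls of the same sex, with null libraries 1 and 3, limma called 241 genes.

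**Figure D4:**
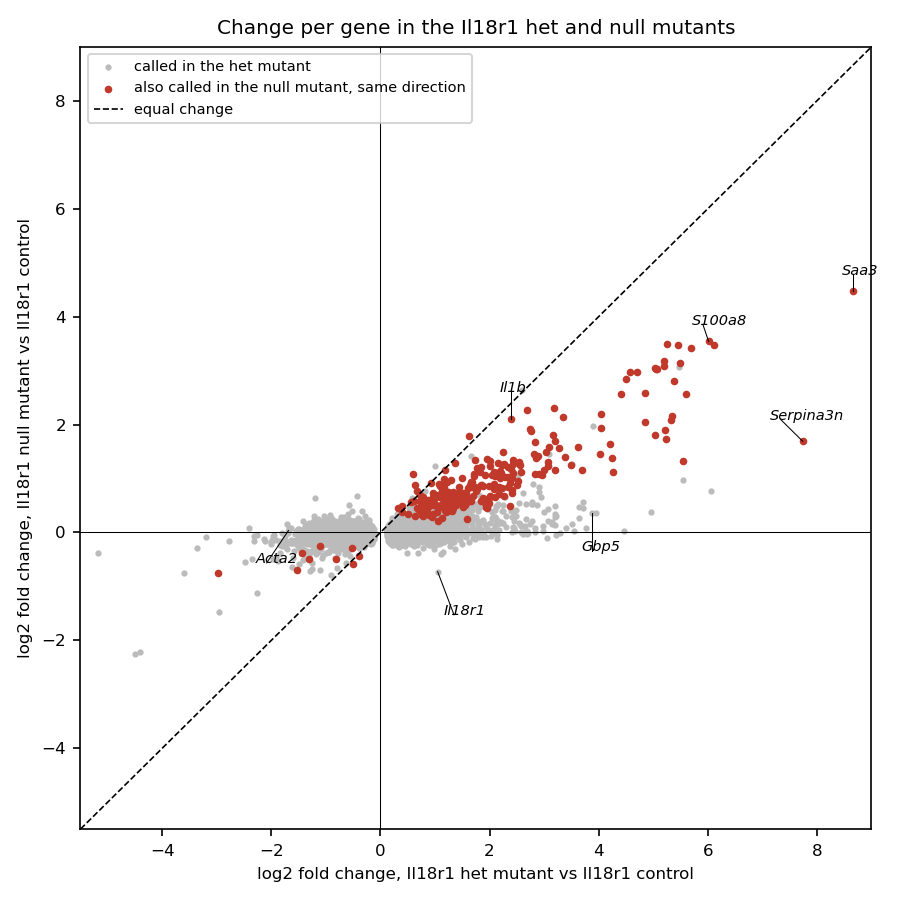
Genes called in the het mutant, 1 point each, with colours for the calls. Axes give log2 fold changes against the Il18r1 control in the het mutant (horizontal) and null mutant (vertical), on the log2(FPKM + 1) scale. S100a8 lies at 6.02 and 3.54 and Acta2 at -1.69 and 0.035 on the 2 axes.

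The fourth comparison set the 2 mutants of the second experiment against each other, and so asked what losing the remaining copy of Il18r1 changed. S100a8 and Saa3 were lower in the null mutant, S100a8 going from 5085 ± 1609.7 (SD, n = 3) to 890.5 ± 118 FPKM (SD, n = 4) and Saa3 from 4108 ± 1049 (SD, n = 3) to 227 ± 76.2 FPKM (SD, n = 4). Acta2 was higher, from 87.2 ± 11.3 (SD, n = 3) to 289 ± 24.7 FPKM (SD, n = 4), as was Rrm2, from 8.60 ± 2.84 (SD, n = 3) to 26.8 ± 3.58 FPKM (SD, n = 4). The surfactant protein gene Sftpa1 was lower, from 1405 ± 95.0 (SD, n = 3) to 645 ± 50.8 FPKM (SD, n = 4). With limma 7311 of 13724 genes (53.3%) passed, 3675 higher and 3636 lower in the null mutant, 811 of them by at least 1 in log2 (292 higher and 519 lower). Groups did not overlap in 7162 tested genes, where chance gives 2 in 35.

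Il18r1 went from 30.6 ± 0.667 (SD, n = 3) to 8.26 ± 0.885 FPKM (SD, n = 4) (log2 fold change -1.78, SE 0.073, adjusted p = 2.7e-08). Il18 fell (log2 fold change -0.75, SE 0.15, adjusted p = 0.00157) and so did Lyz2 (log2 fold change -0.78, SE 0.21, adjusted p = 0.00738). Il1b was at 35.5 ± 6.24 (SD, n = 3) and 30.9 ± 14.2 FPKM (SD, n = 4) and did not pass (log2 fold change -0.30, SE 0.29, adjusted p = 0.415). Nlrp3 (log2 fold change -0.011, SE 0.20, adjusted p = 0.966) and Tnf (log2 fold change -0.34, SE 0.18, adjusted p = 0.119) did not pass.

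Neutrophil markers (15 of 18 lower, median -1.62), granule precursor genes (10 of 10 lower, median -1.71), acute phase and antimicrobial genes (16 of 18 lower, median -1.69), IL-17 response genes (7 of 8 lower, median -1.09), inflammasome and IL-1 family genes (16 of 23 lower, median -0.54), TNF and NF-kB response genes (18 of 29 lower, median -0.77) and matrix proteases and inhibitors (3 higher and 10 lower of 17, median -0.63) were lower in the null mutant. For these lists camera gave adjusted p between 2.4e-09 and 0.0361, and adjusted p between 0.157 and 0.302 with an estimated correlation. Ifitm6 went from 526 to 55.9 FPKM and Il1r2 from 48.3 to 3.03. Hp (-2.91, SE 0.12) and Serpina3n (-6.05, SE 0.31) fell. Interferon-gamma response genes (22 of 26 lower, median -1.92) and type I interferon response genes (2 higher and 13 lower of 22, median -0.79) were lower. The camera test gave adjusted p between 6.7e-07 and 0.00350 for these lists, and adjusted p between 0.330 and 0.560 with an estimated correlation. Gbp5 went from 47.6 ± 50.1 (SD, n = 3) to 2.03 ± 0.568 FPKM (SD, n = 4). Without het library 3, 21 of 25 interferon-gamma response genes fell and 4 rose, with a median of -1.52. Interstitial macrophage markers (13 of 14 lower, median -1.18), alveolar macrophage markers (1 higher and 13 lower of 17, median -0.79) and platelet and megakaryocyte genes (8 of 8 lower, median -1.35) were lower. With camera these lists had adjusted p between 3.7e-07 and 8.7e-04, and adjusted p between 0.157 and 0.302 with an estimated correlation. B cell markers (6 of 8 higher, median 0.88), erythroid genes (7 of 9 higher, median 0.69), dendritic cell markers (6 higher and 1 lower of 9, median 0.61), type 2 lymphoid, mast cell, basophil and eosinophil markers (4 higher and 1 lower of 8, median 0.60) and thymus genes (2 of 2 higher, median 0.80) were higher. Camera gave adjusted p between 3.5e-04 and 0.0461 for these lists, and adjusted p between 0.227 and 0.422 with an estimated correlation. Cd79a went from 0.538 to 6.20 FPKM. Monocyte markers (4 higher and 6 lower of 14, median -0.031 and 0.17 at equal total FPKM, mean 0.080, camera direction lower) and T and NK cell markers (4 higher and 1 lower of 10, median 0.51) were not called by camera. Ccr2 rose (log2 fold change 1.14, SE 0.17, adjusted p = 1.5e-04) and F13a1 fell (log2 fold change -1.43, SE 0.085, adjusted p = 2.5e-07). As adjusted over the list alone, these counts were the same except for neutrophil markers (16 lower), type I interferon response genes (2 higher and 15 lower), monocyte markers (5 higher and 6 lower), alveolar macrophage markers (1 higher and 14 lower), type 2 lymphoid, mast cell, basophil and eosinophil markers (6 higher and 1 lower) and erythroid genes (8 higher).

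Surfactant-making type 2 (AT2) markers (16 of 18 lower, median -0.75), type 1 alveolar epithelial (AT1) markers (1 higher and 18 lower of 19, median -0.58), markers of transitional epithelium (2 higher and 12 lower of 15, median -0.53), airway epithelial markers (9 of 14 lower, median -0.69), mesothelial markers (7 of 8 lower, median -0.81) and hypoxia and glycolysis genes (1 higher and 11 lower of 17, median -0.34) were lower. For these lists camera gave adjusted p between 2.7e-07 and 0.00134, and adjusted p between 0.157 and 0.330 with an estimated correlation. Pdpn went from 147 to 68.4 FPKM and Abca3 from 89.1 to 42.7. Alveolar myofibroblast and smooth muscle markers (15 higher and 2 lower of 18, median 0.76), pericyte markers (10 of 10 higher, median 0.74), elastic fibre and matrix assembly genes (19 higher and 2 lower of 25, median 0.65), proliferation genes (26 of 26 higher, median 1.18) and angiogenesis and alveolar growth factor genes (16 higher and 4 lower of 31, median 0.25) were higher. The camera test gave adjusted p between 1.5e-10 and 0.0195 for these lists, and adjusted p between 0.157 and 0.236 with an estimated correlation. Tnc went from 36.5 to 148 FPKM and Col1a1 from 58.6 to 142. Pan-endothelial markers (5 higher and 2 lower of 13, median 0.15), general capillary markers (3 higher and 4 lower of 13, median 0.068, mean 0.026, camera direction lower), aerocyte (alveolar capillary) markers (5 higher and 6 lower of 13, median 0.076, mean -0.056, camera direction lower), alveolar and lipofibroblast markers (6 higher and 6 lower of 16, median 0.050, mean -0.030, camera direction higher), TGF-beta response genes (6 higher and 3 lower of 16, median 0.19), surfactant lipid synthesis genes (6 higher and 10 lower of 20, median -0.21), heart and skeletal muscle genes (2 higher and 2 lower of 13, median -0.63) and fat cell genes (1 of 2 lower, median -0.063 and 0.72 at equal total FPKM) were not called by camera. Of heart and muscle genes, the calls of Actc1 and Nppa each ended in 6 of 7 fits without 1 library (adjusted p of up to 0.154 and 0.156). Of the lists read for quality, handling genes (2 higher and 7 lower of 15, median -0.44) moved, and of sex-linked genes limma called 0 of 5, with 4 at unadjusted p under 0.05. With p adjusted over the list alone, these counts were the same except for surfactant lipid synthesis genes (6 higher and 12 lower), pan-endothelial markers (5 higher and 3 lower), heart and skeletal muscle genes (1 higher and 1 lower) and immediate early and handling genes (2 higher and 8 lower).

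Among the largest rises were Crabp1 (0.396 to 11.2 FPKM, log2 change 3.10, SE 0.26), Ptpn5 (3.08, SE 0.10), Slitrk6 (2.63, SE 0.14), Prss35 (2.49, SE 0.18) and Etv4 (2.25, SE 0.11), and among the largest falls Serpina3f (117 to 1.65 FPKM, log2 change -5.29, SE 0.35), Chil3 (-4.57, SE 0.41), Cxcl13, a chemokine that attracts B cells, (52.4 to 3.48 FPKM, log2 change -3.59, SE 0.19) and Tgtp2 (-3.69, SE 0.42). Clca1 and Snord22 were listed at 0 in every het library, so no fold is given. Camera called 28 of 38 lists, 10 higher and 18 lower. All 27 also called in het against control moved oppositely, as shared het libraries favour. With an estimated correlation the lowest adjusted p was 0.157, and fry called 33. At equal total FPKM limma called 6961 genes higher and 2037 lower (77.4% higher, against 50.3%), with a median of 0.19 in place of 0.0066. Between the het libraries and null libraries 2 and 4, all with Xist, it called 6344.

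The change of the first experiment was then followed in the second, with other libraries and controls. In the het mutant against its control the 3746 genes higher in the first mutant had a median of 0.40 and the 3734 lower ones -0.37, and limma called 2758 of the former higher and 2818 of the latter lower (camera p = 5.1e-80 and 2.6e-70, p = 3.8e-05 and 3.3e-04 with an estimated correlation). In the null mutant against control the medians were 0.017 and -0.026, with 217 and 6 called in those directions (camera p = 2.5e-06 and 6.4e-04, p = 0.0787 and 0.285 with an estimated correlation). The fry p was 0.0599 and 0.329 for that comparison. Restricted to the smallest p, the higher genes had a median of 0.16, with 16 called higher (p = 0.0327 with an estimated correlation, fry p = 0.00771). In null against het the medians were -0.38 and 0.34 (camera p = 3.4e-78 and 5.6e-73, p = 4.1e-05 and 2.9e-04 with an estimated correlation). Across 13443 genes tested in both experiments, which are not independent replicates, the changes of the first mutant and the het mutant correlated with Pearson's r = 0.872 and Spearman's rho = 0.849. Of 5624 genes called in both, 5576 (99.2%) had the same sign. In both comparisons mutants had Xist and controls did not, so sex may add to this. For null against control r was 0.400 and rho 0.210, with 223 of 226 genes called in both of the same sign.

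Within the second experiment, 6639 of the 7716 genes called in het mutant against control (86.0%) were also called in null against het in the opposite direction, and 257 (3.33%) were called in null against control in the same direction. These comparisons share libraries. Simulations without effects called too few genes (a mean of 0.05 in het against control over 20 draws) to give a reference for these numbers. Opposite calls were 3268 lower and 3371 higher in the null mutant, and same-direction calls 247 higher and 10 lower. Shared libraries favour both, so independent lists give no reference either. Across genes the het and null changes against the shared control had r = 0.592 (simulated 0.459) and a covariance of 0.0888 (simulated 0.00594). For het against control and null against het, r was -0.934 (simulated -0.57) and the covariance -0.317 (simulated -0.00798). With the 4 controls split so that each mutant had 2 of its own, the 6 splits gave r between 0.472 and 0.546, covariances between 0.0787 and 0.0863, and 141 to 176 genes called in both with the same sign. The authors' deposited tables held 8352 genes with adjusted p under 0.05 for het against control, 649 for null against control and 7620 for null against het. These included 92.5%, 97.4% and 90.3% of the limma calls among genes with an adjusted p in both, each with the same sign.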

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

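Tests of sex, and the comparisons within 1 sex, were chosen only after the result was seen; the counts over other splits of the libraries were planned. A library stood apart from the other 3 of its group in 14 of 184 gene and group pairs, by the gap to its neighbour over the group's range of log2(FPKM + 1) (in parentheses, after FPKM); chance gives about 1 in 20. In the Il18r1 control, Lyz2 was at 909.9 in library 1 against 1691 to 1892 (0.846) and Il1r2 was at 0.422 in library 2 against 0.108 to 0.130 (0.923). BC100530 was at 35.8 in library 4 against 52.6 to 54.0 (0.935) and Snord22 was at 41.7 in library 3 and listed at 0 in the others (1). Mmp9 was at 3.04 in library 1 against 1.86 to 1.98 (0.883). In the null mutant, S100a8 was at 714 in library 4 against 942 to 963 (0.927) and S100a9 was at 1286 in library 4 against 1775 to 1808 (0.945). Nr4a1 was at 32.3 in library 1 against 111 to 133 (0.870) and Snord22 was at 104 in library 3 against 45.1 to 50.5 (0.864). Wfdc21 was at 19.5 in library 4 against 34.0 to 37.3 (0.859) and Mrps36 was at 16.8 in library 2 against 15.4 to 15.5 (0.903). Tgtp2 was at 9.11 in library 1 against 2.78 to 3.16 (0.901) and P2ry14 was at 157 in library 1 against 172 to 175 (0.852). Slc2a1 was at 10.8 in library 4 against 12.4 to 12.6 (0.938). Also 35 genes moved one way in every Nlrp3 mutant library and the other way in every het mutant library relative to all their controls, with a log2 change of -0.54 and 1.92 for Iigp1 and -0.65 and 1.30 for Ciita, chosen after their values were seen, and this difference was not tested.

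Chance as the source of the calls was tested by counting genes over other splits of the same libraries. For the Nlrp3 mutant against control, 1 of 10 splits, the real one with 7528 genes, was as large, the highest other called 1, and 10 splits are too few for a share under 0.05. In the second experiment the real split was the largest of 35 each time, which argues against chance but cannot exclude it. Counts were 7716 for het against control (highest other 2206), 270 for null against control (1) and 7311 for null against het (3469). The highest others of het against control and of null against het each kept all but 1 library in its own group.

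A difference in sex may lie behind calls in the het mutant, since its libraries carried Xist and its controls Y-linked transcripts. Within the null group, over 7711 genes called in het against control, the difference between libraries with Xist and those with Y-linked transcripts, signed by the het change, had a median of -0.0246 (SD 0.145 over genes), against a median absolute het change of 0.423, which argues against sex as the main source. Between libraries that all carried Xist, null minus het had a median of 0.343 over genes lower and -0.383 over genes higher in the first mutant, 0.727 apart, so that difference is present within 1 sex. An effect of sex that appears only together with an intact Il18r1 copy stays open, as does sex in the first experiment, where every mutant library carried Xist and every control Y-linked transcripts.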

How the results depend on the processing

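Rescaling to equal total FPKM, sex as a covariate and comparisons within 1 sex were chosen after the data were seen; other alternatives were planned. Of 10233 values of named genes under alternatives, 9987 kept their direction and their side of the threshold, 61 passed where they had not, 183 no longer passed and 2 changed sign. The 2 were the Y-linked Kdm5d (0.023) and Uty (0.029) in het against control with sex as a covariate, which by construction takes up their difference. Total counts of genes stayed within 1.5 times except as follows; the split into higher and lower moved more at equal total FPKM. With a log2 change of at least 1, the 4 comparisons kept 1096, 1067, 103 and 811 genes, as a stricter limit must. With sex as a covariate het against control gave 4883 genes; that fit leans on 4 null libraries to separate sex. Null against control gave 177 genes at a mean of at least 5 FPKM, where fewer genes were tested, and 420 with a robust fit and array weights; its 14 lower genes numbered 6 with the replicate block and 52 in that robust fit; the cause was not tested here. At a mean of at least 5 FPKM, 168 genes of the het change were called in null against control in the same direction. With an estimated correlation, camera called 0, 0, 7 and 0 lists in the 4 comparisons, where fry called 29, 33, 9 and 33 and camera at unadjusted p under 0.05 3, 10, 10 and 8. The lower genes of the first experiment, restricted to the smallest p, had a median of -0.015 in null against control and no longer passed with camera; the cause was not tested.

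Leaving out each library in turn gave 5930 to 6940 genes for the Nlrp3 mutant, 6815 to 7640 for het against control, 206 to 270 for null against control and 6398 to 7203 for null against het. The genes of the het change that moved back in the null mutant numbered 5812 to 6623, and those called in both mutants 194 to 295. Replicate numbers did not pair the samples: correlations of deviations between same-numbered samples were -0.101 to 0.269, and at most 1 sample per comparison correlated best with its own number. With the number as a block, limma called 7009, 7278, 225 and 6807 genes, with 6207 of the het change moved back and 215 called in both. FPKM keeps no read totals, so what depth limits for single low genes could not be set out.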

Other observations

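In null against control, limma called 13 genes that were not called in the same direction in the het mutant, and the genes named here were chosen after their values were seen. They included Ccr2 (7.24 to 19.4 FPKM, log2 change 1.30, adjusted p = 5.5e-04), Clec7a (15.4 to 25.6 FPKM, log2 change 0.72, adjusted p = 0.00813), a receptor for fungal glucans, S100a4 (32.0 to 52.2 FPKM, log2 change 0.68, adjusted p = 0.00158) and Malat1 (100.4 to 196 FPKM, log2 change 0.95, adjusted p = 2.1e-05), a nuclear non-coding RNA. In the het mutant the log2 changes were 0.16, 0.22, -0.43 and -0.13, of which S100a4 passed (adjusted p = 0.00352). Null against het also called each of Ccr2 (1.14, adjusted p = 1.5e-04), Clec7a (0.50, adjusted p = 0.00830), S100a4 (1.11, adjusted p = 4.6e-06) and Malat1 (1.08, adjusted p = 1.3e-06).

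The tests on the end of the X chromosome were chosen only after the result was seen; those on glucocorticoid targets not yet looked at were written before. Within the null group, 7 neighbouring genes from Tmsb4x to Hccs (chromosome X, 167207093 to 169320372, GRCm38, 2.11 Mb) were higher in libraries with Y-linked transcripts, by a median of 0.887 in log2 and by ratios of mean FPKM of 1.79 to 2.67, and 5 of them passed. A chance run of X genes is argued against by 412 other windows of as many genes, whose highest absolute median was 0.137. The 7 genes just before the block had a median of -0.061. A candidate explanation is an extra copy of the segment in males, as in the Yaa allele. In the comparisons that did not choose the block, control (Y-linked transcripts) minus mutant (Xist) had medians of 0.566 (SD 0.650 over genes) for the het mutant and 0.549 (SD 0.402) for the Nlrp3 mutant, below the 1 that a doubled dose would give. There sex goes with genotype, so an extra copy and other dosage differences stay open.

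Genes that glucocorticoids induce were higher in both mutants: after 6 targets seen first had risen in each, 18 others were tested, of which limma called 17 higher and 1 lower in the Nlrp3 mutant (median 1.20, fry p = 1.2e-04, camera p = 0.0666 with an estimated correlation) and 16 and 1 in the het mutant (median 1.14, fry p = 1.7e-05, camera p = 0.0891; by library, looked at afterwards, medians were 0.66, 1.5 and 1.13 and Fkbp5 at 11.5, 42.0 and 44.6 FPKM in libraries 1, 2 and 3). In null against control limma called 0, with 2 at unadjusted p under 0.05 (median -0.018). For null against het limma gave 1 higher and 16 lower (median -1.10, fry p = 1.9e-05, camera p = 0.0833 with an estimated correlation). Higher glucocorticoid exposure may explain the rise in both mutants, as may other causes. The fall in null against het shares het libraries and is no separate test. Time of day at sampling stays open, as clock genes of opposite phase moved apart by 0.831 in the Nlrp3 mutant and 1.17 in the het mutant, where all targets had medians of 1.46 and 1.29. Handling before lysis is not excluded: immediate early genes had medians of 0.482 (SD 0.867 over genes) and 0.326 (SD 0.944), under 0.5 of those of the targets, but members moved both ways and the distance to 0.5 was within their SD.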
